A study of Homo sapiens with 8 samples.

How the data were processed

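The deposited values were processed expression tables, 1 for day 0 of both tumours and 1 for the later day of each tumour, made from 10x Genomics libraries with Cell Ranger 3.0.2 and GRCh38 per the submitters' processing notes. The values were ln(1 + counts per 10000) as normalized by the authors, although the files are named as counts, so the unit differed from the one planned before the data were examined. Whole UMI counts were recovered per cell by undoing the natural log and dividing by the smallest step of the cell, using values of up to 20 UMIs. The median share of recovered values within 0.1 of a whole number was 99.7% to 100% across libraries and 74.9% in the worst cell. Cell class and library number were read from the cell names, and none was inferred from values.

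Cells with fewer than 500 UMIs, fewer than 200 genes or more than 20% mitochondrial RNA would have been left out, but the deposited cells passed all 3 limits. Scrublet, as implemented in scanpy 1.11.5 because the separate package was absent, ran on each library with an expected doublet rate of 6%. Marks were used where they reached 0.5% of a library. It marked 20 cells in the day 0 library of tumour 3, which were left out, and at most 1 cell in each of the 7 other libraries, whose marks were not used.

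The level of a gene in a class is its mean count per 10000 over the cells of the class, and the fold is the ratio of means. A gene was named only with 50 or more UMIs on its higher side. A side with no UMI took a floor of 3 UMIs over its group and gave a bound written as "at least". Genes were named where every library of 1 side lay above every library of the other and both tumours, if compared, had the same direction, ranked by the smaller ratio with up to 10 in each direction. Y-linked, mitochondrial, ribosomal protein and immune receptor variable genes were never named, and polymorphic gene families were also left out where the 2 tumours, which are 2 people, were compared. List medians came from 16 programme lists and were given for lists with 4 or more measured members, with the rank of the median among 10000 random lists drawn within 50 expression ranks of each member. Class names were checked with 13 marker lists. The naming rule, the minimum and floor in UMIs, the lists and the random lists were fixed before the data were examined. The mean count per 10000 replaced the planned scaled sums of counts once the unit was seen. The comparisons kept, the lists shown for each class and the polymorphic families left out were chosen after values were seen.

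The check of class names first took the fold of a gene against the highest other class. After 3 classes led with markers of another class, the fold was taken against all other cells. The regulatory T cells of tumour 3 at day 11 then held 1 dendritic and 1 regulatory T marker among their leading genes, and the 2 classes of CD14-negative myeloid cells at day 0 held 3 dendritic markers each.

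The method was tried on simulated cells in which 200 genes were changed, and genes with enough UMIs were counted. All simulated cells of a side were drawn from the same profile and differed only in depth and counting error. The counts below thus do not cover real variation between cells or libraries, or RNA from other cells. In macrophages 84 of 85 genes changed 2-fold and 84 of 84 changed 4-fold had the right direction in tumour 1, and 96 of 96 and 99 of 99 in tumour 3. In T cells these counts were 96 of 99 and 93 of 93 in tumour 1, and 92 of 96 and 92 of 92 in tumour 3. Unchanged genes also had all later libraries on 1 side of day 0 in 3840 of 8059 cases in macrophages of tumour 1 and 11850 of 13995 in its T cells. Having all libraries on 1 side is therefore a weak filter with a single day 0 library. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.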

Results

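Needle biopsies of 2 human non-small cell lung cancers, named tumour 1 and tumour 3 in the labels, were profiled by droplet single-cell RNA sequencing. Each tumour gave 1 sample at day 0 and 3 samples at a later day, which was day 7 for tumour 1 and day 11 for tumour 3. The later samples carry the labels of an isotype control antibody, durvalumab, which blocks PD-L1, or durvalumab with tremelimumab, which blocks CTLA-4. The labels do not say how samples were kept between the days, nor how cell classes were assigned. Later cells carry a library number from 1 to 3 that the labels do not tie to an antibody, so the antibodies were not compared and the 3 later libraries of a tumour are given as a range. The day 0 library held 2731 cells with a median of 2539 UMIs in tumour 1 and 1727 cells with a median of 28262 UMIs in tumour 3. Later libraries held 9299 to 11050 cells with medians of 12668.5 to 13873.5 UMIs in tumour 1, and 4223 to 4944 cells with medians of 9678 to 10829.5 UMIs in tumour 3. No test was planned for cells that cannot be tied to a sample and none was run, so every difference is a description of these libraries. The 95% intervals, which are Clopper-Pearson intervals for shares, cover counting error only. A fold written as "at least" sets the measured mean of 1 side against a floor of 3 UMIs over the other side, which had none, and leaves out the counting error of the measured mean.

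To see which cells the biopsies held, the cell classes written by the authors in the cell names were counted at each day. At day 0, tumour 1 was mostly immune, with 25.6% macrophages (23.9 to 27.2), 24.3% T cells (22.7 to 26.0), 17.6% CD14-negative myeloid cells and 11.3% plasmacytoid dendritic cells, and only 2.49% tumour cells (1.94 to 3.15). Tumour 3 held 40.7% tumour cells (38.4 to 43.1), 30.8% fibroblasts and endothelial cells (28.6 to 33.0), 19.2% macrophages (17.4 to 21.2) and 2.58% T cells (1.88 to 3.45). B cells made up 9.59% and plasma cells 4.76% of tumour 1, against 2 B cells in all and 4.92% plasma cells in tumour 3, and mast cells (3.95%) were labelled only in tumour 1. Known markers were high in the classes named for them. JCHAIN stood at 107 counts per 10000 (cp10k) in plasma cells of tumour 1, TPSAB1 at 166 cp10k in its mast cells, MS4A1 at 6.88 cp10k in its B cells and COL1A1 at 145 cp10k in the fibroblast and endothelial class of tumour 3.

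At the later days natural killer (NK) cells were the largest class in both tumours, and no later cell carried a tumour cell label. NK cells made up 62.4% to 64.8% of the tumour 1 libraries at day 7 and 37.2% to 54.3% of the tumour 3 libraries at day 11, with GNLY, a granule protein of killer cells, at 43.2 and 23.5 cp10k. CD8 T cells followed with 19.0% to 20.1% in tumour 1 and 17.8% to 21.8% in tumour 3. Conventional CD4 T cells ranged from 5.99% to 8.16% in tumour 1 and from 7.45% to 23.1% in tumour 3, and regulatory T cells from 3.07% to 3.37% and from 2.16% to 5.38%. Cells named undefined by the authors made up 1.60% to 1.82% in tumour 1 and 8.95% to 10.9% in tumour 3. Myeloid cells, the class nearest to the day 0 macrophages, made up 0.878% to 1.03% in tumour 1 and 0.607% to 1.21% in tumour 3. B and plasma cells together were 2.66% to 2.97% and 3.11% to 3.44%, and fibroblasts were labelled only in tumour 3, at 0.384% to 0.995%. The class names differ between the day 0 table and the later tables, so only the macrophage share was set against the later days.

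**Figure D1:**
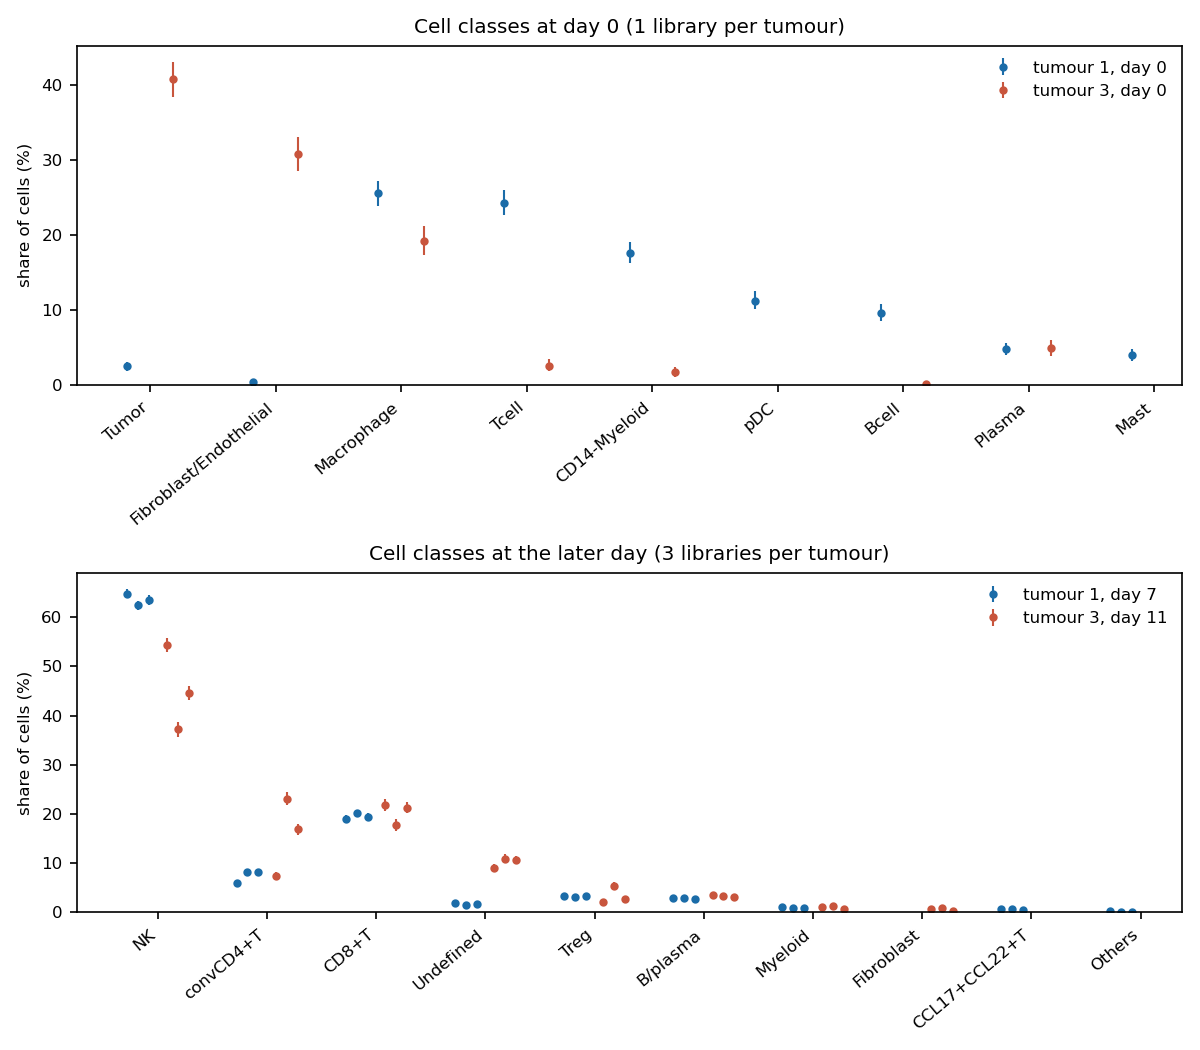
Share of cells in each class named by the authors, for the day 0 library and the 3 later libraries of each tumour. Each dot is a single library and each line its Clopper-Pearson interval.

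How tumour macrophages differed between day 0 and the later day was examined first, because these cells can either present antigen to T cells or restrain them. The later cells, named myeloid by the authors, had far less RNA of inflammatory, stress and MHC class II genes, and more RNA of metallothioneins. IL1B, the inflammasome cytokine, stood at 0.00861 cp10k later against 18.9 cp10k at day 0 in tumour 1 (2196-fold lower) and at 0.0126 against 9.46 in tumour 3 (753-fold lower). CD163, a scavenger receptor of tissue macrophages, was 0.0465 against 4.89 and 0.0335 against 2.85 cp10k. CCL22, a chemokine that draws regulatory T cells, was 4.08 against 0.187 and 4.76 against 0.0951 cp10k. At day 0, however, CCL22 was a leading gene of the separate CD14-negative myeloid class in both tumours. No class of that name exists at the later days, so the CCL22 difference may follow how the classes were split. The day 0 and later tables were normalized separately, each to 10000 counts per cell, and this holds for every later-against-day 0 level.

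Among the genes lower in later macrophages of both tumours were the chemokine CCL20, the growth factor AREG, the complement receptor VSIG4, the matrix proteoglycan VCAN and the activating receptor TREM1. CCL20 was 0.00323 against 3.98 cp10k in tumour 1 (1234-fold, interval 336 to 10058, 2 later UMIs) and 0.0014 against 5.68 in tumour 3 (4043-fold, interval 480 to 105786, 1 later UMI), where folds come from mean levels and intervals from UMI sums, so that a fold can lie outside its interval if a few cells hold most UMIs. AREG was 2038-fold lower in tumour 1 and 478-fold lower in tumour 3 (interval 195 to 2764), and VSIG4 325-fold (98.0 to 21926) and 691-fold lower (159 to 4756). VCAN was 553-fold (142 to 31696) and 263-fold lower (56.3 to 12464), and TREM1 had no later UMI in tumour 1 against 1.11 cp10k at day 0 (at least 248-fold) and was 213-fold lower in tumour 3. The immediate-early gene NR4A1 was 0.0262 against 4.86 and 0.00820 against 5.59 cp10k, the signalling regulator RGS2 0.0230 against 4.75 and 0.0126 against 10.8, and the inducible heat shock gene HSPA6 0.0232 against 4.67 and 0.0264 against 5.11. The ribokinase RBKS was 195-fold lower in tumour 1 and 286-fold lower in tumour 3 (50.8 to 724).

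The largest differences in the other direction were in genes with almost no RNA at day 0. The neuropeptide gene GAL was 5.59 cp10k later (5.34 to 5.79 across libraries) against none at day 0 in tumour 1 (at least 457-fold) and 21.3 (13.7 to 32.5) against 0.00243 cp10k in tumour 3 (8774-fold, interval 2074 to 29401). AK8, an adenylate kinase, was 2.32 against 0.00257 cp10k (900-fold, interval 84.9 to 2539) and 2.00 against 0.00393 (510-fold, interval 213 to 3030). CRABP2, which carries retinoic acid into the nucleus, was 99.0-fold higher in tumour 1 (59.2 to 841) and 96.6-fold in tumour 3, and UCHL1, a deubiquitinase, 273-fold (33.2 to 473) and 57.0-fold. The long noncoding RNAs RP11-20G13.3 and LINC00520 were 686-fold (135 to 1920) and 345-fold higher (119 to 1696) in tumour 1, and 270-fold and 149-fold higher in tumour 3. Part of the later RNA came from lymphocytes, since TRDC, a T cell receptor gene, was 0.639 against 0.0130 and 0.879 against 0.000866 cp10k, and GNLY 3.74 against 0.281 and 2.15 against 0.041 cp10k. The cytotoxic list, made of lymphocyte genes, had medians of 3.73 and 5.20 in the later class (7 of 8 higher in each tumour), and proliferation genes had 3.97 (12 of 12) and 3.59 (8 of 9), all above every random list. After thinning each cell to 500 UMIs the proliferation medians were 1.71 and 1.31 and the cytotoxic median of tumour 3 was 3.64.

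The gene lists grouped these differences by function. The immediate-early and heat shock list had a median log2 ratio of -6.29 in tumour 1 and -5.29 in tumour 3, with 11 of 11 genes lower in both and below all 10000 random lists matched on expression. FOS was 0.262 against 20.7 and 0.411 against 16.1 cp10k, HSPA1A 0.451 against 35.2 and 0.268 against 84.1, and JUN 1.10 against 12.2 and 1.30 against 16.6. Type I interferon response genes were lower, with medians of -2.08 and -2.22, with 13 of 14 genes lower in both tumours, such as ISG15 (0.499 against 3.72 and 0.228 against 5.62 cp10k) and MX1 (0.419 against 1.63 and 0.127 against 0.708). MHC class II genes were lower at -2.88 and -3.19, 10 of 10 in both, with HLA-DRA at 10.1 against 71.9 and 10.1 against 133 cp10k, CD74 at 21.5 against 180 and 27.6 against 274, and their regulator CIITA at 0.281 against 0.648 and 0.189 against 0.525. MHC class I genes were near even in tumour 1 (-0.16, 6 of 10 lower) and slightly lower in tumour 3 (-0.57, 7 of 10).

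Neither pole of the M1-like and M2-like division of macrophages was higher, since both lists were lower, M1-like by -3.26 and -3.89 (8 of 9 genes lower in both tumours) and M2-like by -5.38 and -4.14 (8 of 11). After thinning each cell to 500 UMIs, the M1-like median of tumour 3 was -2.62 and the M2-like medians were -1.70 and -2.10. Which of the lists was lower in tumour 3 thus changed with thinning. Thinning leaves the expected share of a gene in a cell's UMIs unchanged, so this change does not show an effect of depth. IL6 (0.00807 against 0.897 and 0.0192 against 0.513 cp10k) and IL10 (0.0203 against 2.75 and 0.0248 against 0.615) were lower together, and TNF stood at 0.301 against 0.606 and 0.480 against 0.939 cp10k. Chemokine genes were lower at -4.21 and -3.31 (the latter -4.30 from summed UMIs), 9 of 10 in both tumours: CCL3 2.37 against 29.7 and 2.40 against 21.0 cp10k, CCL4 2.07 against 51.1 and 2.66 against 24.4, and CXCL8 1.58 against 22.0 and 1.29 against 23.6. The exception was CCL5, at 2.49 against 0.827 and 7.90 against 0.494 cp10k, which was not separated from the lymphocyte RNA in this class. Hypoxia genes were lower at -1.12 (-0.44 after thinning each cell to 500 UMIs) and -1.60, with VEGFA at 0.0387 against 3.68 and 0.0356 against 1.79 cp10k.

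Interferon-gamma targets split in later macrophages, with 11 of 16 lower and 5 of 16 higher in both tumours and list medians of -0.71 and -1.07. The T cell-attracting chemokines CXCL9 (0.0876 against 5.03 and 0.0855 against 10.9 cp10k) and CXCL10 (0.0506 against 7.93 and 0.0142 against 7.24) were lower. WARS (6.61 against 1.11 and 3.13 against 2.44 cp10k), SOCS1 (0.645 against 0.517 and 1.09 against 0.254) and CD274, which encodes PD-L1 (0.597 against 0.105 and 0.432 against 0.174), were higher. In the separate CD14-negative myeloid class of day 0, CD274 stood at 0.259 cp10k in tumour 1 and 0.486 in tumour 3. The CD274 difference, like that of CCL22, may therefore follow how the classes were split. SOCS1 was higher still in later B and plasma cells, so lymphocyte RNA in the macrophage class may carry part of its difference. Metallothioneins, which bind zinc and copper, had medians of 2.21 (6 of 6 higher) and 2.06 (4 of 6, 0.58 to 2.76 across libraries), at percentiles 99.95 and 99.98 of the random lists, with MT1G at 20.4 against 1.24 and 6.80 against 1.23 cp10k and MT2A at 91.6 against 32.5 and 38.7 against 12.0. SPP1, a matrix protein of tumour macrophages, differed by tumour, at 10.2 against 6.03 cp10k in tumour 1 and 3.34 against 59.0 in tumour 3. With every cell thinned to 500 UMIs, the M2-like medians were -1.70 and -2.10, the Type I interferon medians -1.35 and -1.35, and the immediate-early medians -5.15 and -3.84.

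**Figure D2:**
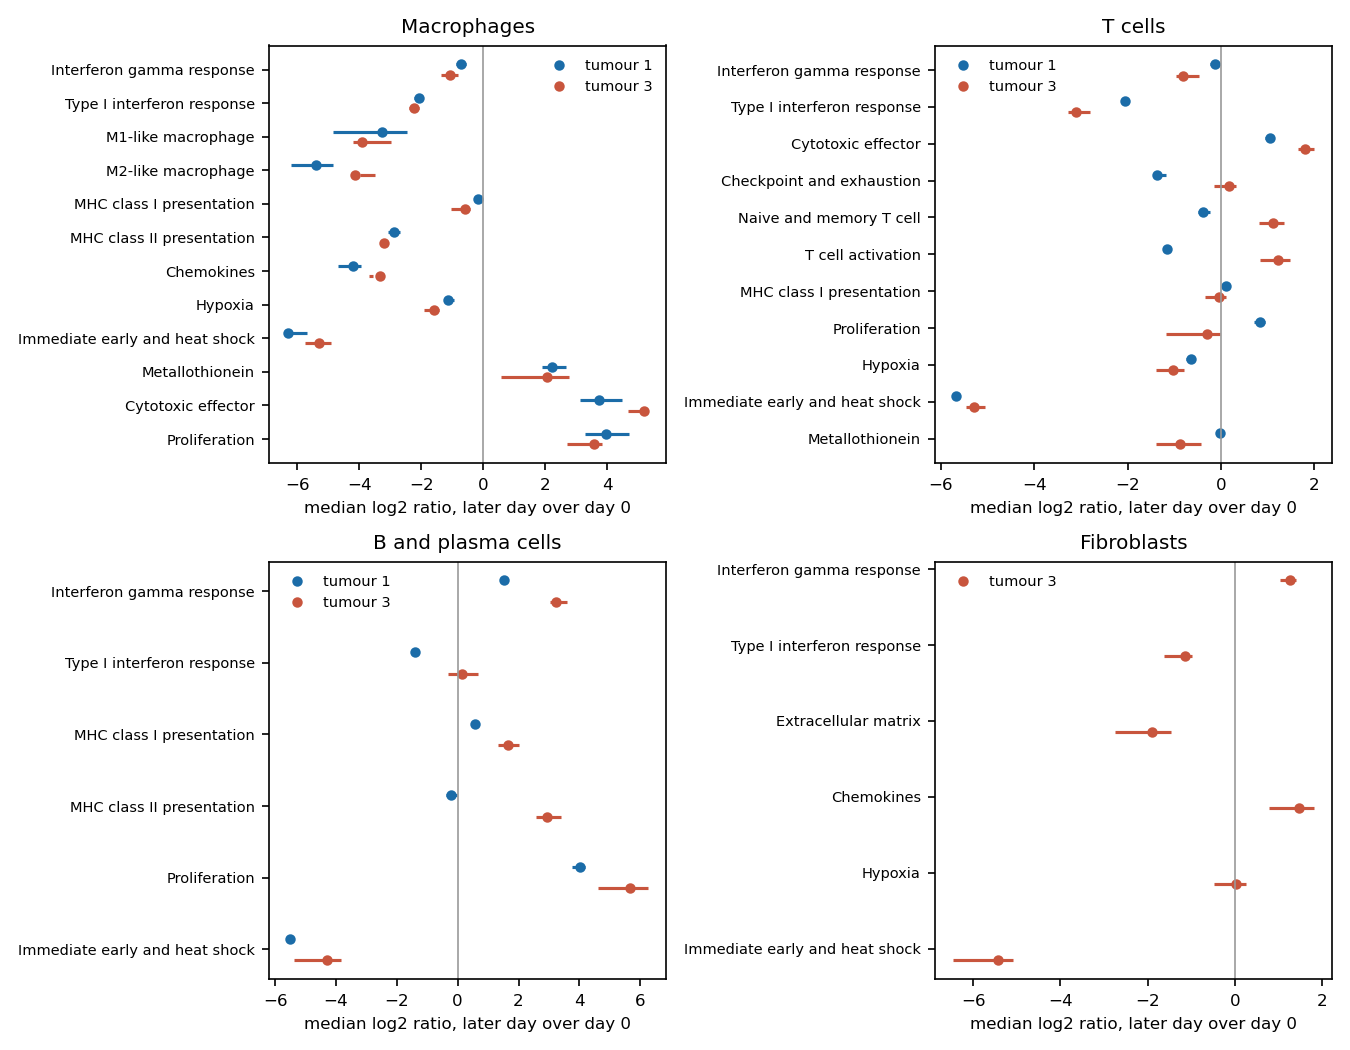
Median log2 ratio of each gene list, later day against day 0, for the classes and lists compared in each tumour, with a line from the lowest to the highest later library. A library's median leaves out members without a ratio in that library, so a dot can lie outside its line.

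To compare T cells over time, the later CD8, conventional CD4 and regulatory T cells were pooled and set against the day 0 T cells, which held 664 cells in tumour 1 and 44 in tumour 3. Later T cells had more LTB and CISH RNA and more RNA of killing genes, and far less of stress genes. LTB, the lymphotoxin that organises lymphoid tissue, was 59.6 cp10k (58.6 to 60.4 across libraries) against 2.08 in tumour 1 (28.6-fold) and 39.4 (36.0 to 42.3) against 0.622 in tumour 3 (63.3-fold). CISH, which cytokine receptors induce through STAT5, was 3.80 against 0.0558 cp10k (68.0-fold) and 3.63 against 0.137 (26.5-fold).

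Other genes higher in later T cells of both tumours were the peptidase DPP4, also called CD26 (17.4-fold and 23.7-fold), the oxidative stress gene NQO1 (27.4-fold and 11.9-fold), the transcription factor MSC (12.6-fold, and 14.1-fold with an interval of 6.72 to 95.4), the actin regulator FAM101B (11.4-fold, and 11.9-fold with 3.53 to 50.1) and the protease MMP25 (28.6-fold with 13.2 to 187, and 35.9-fold with 7.98 to 1759). The cytotoxic list had medians of 1.05 in tumour 1 (8 of 11 genes higher, 0.58 at a mitochondrial limit of 5% and 0.71 after thinning) and 1.81 in tumour 3 (11 of 11). Granzyme and perforin genes led it: GZMA was 9.77 against 1.19 and 7.90 against 1.25 cp10k, GZMB 6.87 against 3.0 and 16.6 against 1.05, PRF1 1.85 against 0.669 and 1.73 against 0.301, and NKG7 13.8 against 4.98 and 13.9 against 1.59. GZMA also stood at 5.19 and 3.51 cp10k in later B and plasma cells, so RNA of other cells was not separated from that of T cells. S1PR1, the receptor for leaving tissue, was 0.510 against 0.129 and 0.475 against 0.0550 cp10k.

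Many of the genes lower in later T cells belong to myeloid or plasma cells and mark RNA of those cells in the day 0 T cell class. The complement genes C1QC (2461-fold in tumour 1 and 5994-fold in tumour 3), C1QB (455-fold and 3936-fold) and C1QA (552-fold and 12904-fold), the neutrophil and monocyte genes S100A9 (440-fold and 720-fold) and SERPINA1 (at least 1745-fold, and 3428-fold), the chemokine CXCL3 (2803-fold and 2125-fold), the transcription factor KLF4 (972-fold and 1527-fold) and the antibody gene IGHA1 (661-fold and 3323-fold) were of this kind. Fewer than 2 C1Q UMIs were seen in 616 of the 664 day 0 T cells of tumour 1 but in only 16 of the 44 of tumour 3. These T cells had medians of 2424 UMIs in tumour 1 and 22395 in tumour 3. The same cut is thus harder to reach in tumour 1, and the counts cannot be compared directly. With the cells holding 2 or more C1Q UMIs left out, the tumour 3 medians were 0.85 for the cytotoxic list, -1.06 for Type I interferon against -3.11 with them, and 0.11 for interferon-gamma targets against -0.82 with them.

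Stress genes were lower in T cells as in macrophages, with immediate-early and heat shock medians of -5.68 and -5.30 and 11 of 11 genes lower in both tumours. FOS was 0.0587 against 16.3 and 0.995 against 33.7 cp10k, and HSPA1A 0.651 against 17.3 and 0.657 against 74.3. The Type I interferon list was lower at -2.05 in tumour 1, 14 of 14 genes, with MX1 at 0.460 against 2.60 cp10k and ISG15 at 1.74 against 3.73. In tumour 3 MX1 was 0.145 against 1.49 and ISG15 0.646 against 5.83 cp10k. Interferon-gamma targets were near even in tumour 1 (-0.13, 9 of 15 lower, but -0.79 with NK cells added to the later T cells), as were MHC class I genes in both tumours (0.12 and -0.04), and hypoxia genes were lower at -0.63 and -1.03. Metallothioneins, higher in later macrophages, were near even in T cells of tumour 1 (-0.02) and lower in tumour 3 (-0.88, 5 of 5).

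Checkpoint, activation and naive and memory genes differed between the tumours, but less so without the C1Q-positive day 0 cells, when tumour 3 had medians of -0.32, 0.42 and 0.36. In tumour 1 the checkpoint list was lower in later T cells (-1.36, 10 of 11 genes), with CTLA4 at 0.311 against 3.11 cp10k, TIGIT at 1.78 against 3.0 and CXCL13, which tumour-reactive T cells make, at 0.576 against 29.1. Tumour 3 gave a checkpoint median of 0.17 with all cells, with CTLA4 at 0.954 against 0.769 cp10k, TIGIT at 1.46 against 0.933 and CXCL13 at 0.309 against 3.63. T cell activation genes had medians of -1.16 and 1.22, with TNFRSF4 (OX40) at 1.56 against 3.49 and 3.12 against 0.604 cp10k and IL2RA at 1.26 against 1.35 and 2.69 against 0.430. Naive and memory genes had medians of -0.39 and 1.13, the latter -0.12 after thinning, with IL7R at 1.21 against 6.24 and 1.5 against 1.93 cp10k. Proliferation genes had medians of 0.84 (12 of 12 higher) and -0.30 (10 of 12 lower), with MKI67 at 3.24 against 1.06 and 1.91 against 1.99 cp10k, and IFNG stood at 0.309 against 1.08 and 0.755 against 0.728. With the later NK class added to the T cells, the tumour 1 naive and memory median was -1.68, the activation median -1.98 and the Type I interferon median -2.64.

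B and plasma cells, which share a class at the later days, were compared with the pooled B and plasma cells of day 0. The later class had more RNA of dividing cells and less of antibody and heat shock genes. TYMS, which makes thymidylate for DNA synthesis, was 1.61 against 0.0376 cp10k in tumour 1 (42.8-fold) and 1.17 against 0.0186 in tumour 3 (62.9-fold), and the antibody gene IGHG3 was 0.460 against 111 (242-fold lower) and 2.75 against 82.1 (29.9-fold lower). Day 0 held 262 B and 130 plasma cells in tumour 1 and 2 B and 84 plasma cells in tumour 3. The later class does not separate B from plasma cells, so their mix was not measured and may carry part of any difference. The later class also held RNA of killer cells, with GZMA at 5.19 and 3.51 cp10k. RNA of other lymphocytes was not separated for any gene or list of this class.

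Proliferation genes in later B and plasma cells had medians of 4.02 (2.15 after thinning) and 5.66, 12 of 12 in both tumours, with MKI67 at 1.87 against 0.0672 and 0.814 against 0.00555 cp10k. The mitotic gene ASPM was 59.0-fold and 164-fold (22.9 to 5083) higher. Interferon-gamma targets were higher by 1.53 (12 of 14) and 3.25 (13 of 14, 1.97 after thinning), among them the guanylate-binding protein GBP4 (3.41 against 0.667 and 2.08 against 0.0643 cp10k), SOCS1 (4.16 against 1.45 and 3.58 against 0.178) and IRF1 (5.69 against 2.06 and 4.07 against 1.61). Most genes of this class were higher later, as random lists show, and MHC class I genes, at 0.56 and 1.66, stood close to random lists matched to them (0.37 and 1.57). Matched random lists had medians of 0.53 and 1.79 for interferon-gamma targets, and of 0.56 and 2.04 for proliferation genes. Part of both differences thus goes with the general shift of the class. MHC class II genes were near even in tumour 1 (-0.21) and higher in tumour 3 (2.94, 10 of 10), where CD74 was 86.7 against 11.9 cp10k but 91.4 against 90.2 in tumour 1. Type I interferon genes were lower in tumour 1 (-1.40, 11 of 13), and in tumour 3 their median of 0.15 lay below all random lists, which had 1.95, and was -1.41 after thinning. CISH had no day 0 UMI in tumour 1 against 1.30 cp10k later (at least 59.5-fold) and was 82.8-fold higher in tumour 3.

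Heat shock genes of B and plasma cells followed the other classes, with list medians of -5.52 and -4.29 (11 of 11) and HSPA1A at 0.345 against 15.8 cp10k (45.9-fold lower) and 0.313 against 69.4 (222-fold). HSPA1B was 105-fold and 298-fold lower, HSPA6 178-fold and 912-fold, and the nuclear receptors NR4A1 28.3-fold and 206-fold and NR4A3 60.7-fold and 34.9-fold. The light chain gene IGLL5 was 42.3-fold and 29.7-fold lower, with intervals of 131 to 161 and 13.9 to 15.6. Myeloid genes were lower too, LYZ by 1068-fold in tumour 1 (534 to 7625) and 153-fold in tumour 3, S100A8 by at least 1164-fold and at least 68.4-fold, and CXCL8 by 214-fold and 59.6-fold. Genes of NK cells, the largest later class, were higher: TRDC 192-fold (55.3 to 1650) and 405-fold (66.1 to 14594), GZMA 96.8-fold and 674-fold (112 to 3338), XCL2 51.4-fold and 193-fold (58.1 to 826) and KLRC1 39.9-fold and at least 74.3-fold.

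Fibroblasts of tumour 3 were compared between day 11 (96 cells) and the day 0 class of fibroblasts and endothelial cells (525 cells), to see whether matrix genes kept their level. Collagen and other matrix genes were mostly lower: COL1A1 was 7.23 against 145 cp10k, COL3A1 3.80 against 81.3, SPARC 2.46 against 59.7 and POSTN 0.727 against 10.8, and the matrix list had a median of -1.90 with 9 of 13 genes lower. MMP9, a gelatinase, was higher (2.34 against 0.0695 cp10k) and TIMP1 near even (37.9 against 35.3). MMP9 is also a leading gene of the later myeloid class in both tumours, and myeloid RNA among the 96 cells was not separated. MMP11 was 837-fold lower, the Wnt antagonist SFRP4 1754-fold (324 to 71415), the calcification inhibitor MGP 251-fold and IGFBP5 201-fold lower than in the day 0 class, which also holds endothelial cells. SERPINB2, an inhibitor of plasminogen activators, was 1.88 against 0.00122 cp10k (1532-fold, interval 511 to 15320), and the growth factor CSF2 was 1.2 cp10k (0.255 to 2.38 across libraries) against none (at least 596-fold).

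Later fibroblasts also differed in interferon and chemokine genes. Interferon-gamma targets had a median of 1.27 (13 of 16 higher), with GBP1 at 3.36 against 1.15 cp10k, while Type I interferon genes had a median of -1.14 (11 of 14 lower). Chemokines split, with a median of 1.46, CXCL5 at 3.80 against 0.101 cp10k and CXCL8 at 7.42 against 2.53, but CXCL12 at 0.325 against 2.83. Immediate-early and heat shock genes were lower at -5.43 (11 of 11), HSPA6 by 651-fold, HSPA1A by 276-fold and HSPA1B by 261-fold, and hypoxia genes were even (0.03). The dendritic chemokine CCL22 (894-fold, interval 95.8 to 21603, with later libraries from 0.0126 to 2.08 cp10k), the lymphotoxins LTA (207-fold) and LTB (149-fold) and CCL5 (9.99 against 0.374 cp10k) were higher, which marks immune RNA among the 96 cells, and the cell cycle genes CCNA2 and CENPA were 153-fold and 148-fold higher.

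Tumour 1 and tumour 3 were then set side by side at day 0, as 2 people with 1 library each in the same table. The classes named tumour cells differed in lineage genes: the surfactant genes of alveolar cells, SFTPC (53.5 against 5.46 cp10k) and SFTPB (21.5 against 2.75), NAPSA (4.07 against 0.539) and their regulator NKX2-1 (0.457 against 0.0399) were higher in tumour 1. The basal keratin KRT5 (4.64 against 28.5 cp10k), KRT19 (4.42 against 29.9), TP63 (0.304 against 0.761) and EPCAM (0.973 against 2.48) were higher in tumour 3. The surfactant genes SFTPC, SFTPB, SFTPA1 and SFTPA2 were leading genes of this class in both tumours, and normal lung epithelium was not separated from tumour cells. The 68 tumour cells of tumour 1 had more RNA of the serine protease inhibitors SERPINB4 (5.09 against 0.00327 cp10k, 1558-fold, interval 450.2 to 1408), SERPINB3 (5.76 against 0.0273, 211-fold, interval 123 to 207) and SPINK6 (4.53 against 0.00039, 11604-fold, interval 1962 to 442106). They also had more of the airway secretory genes BPIFB1 (4.68 against 0.0157, 297-fold, interval 102 to 235) and LTF (6.17 against 0.0399, 154-fold, interval 67.6 to 109). CSF3 (153-fold, interval 219 to 478), STC1 (139-fold, interval 220.2 to 393), EREG (122-fold) and CCL20 (18.1 against 0.212, 85.6-fold, interval 91.5 to 113) were higher as well. KRT13 and SPRR2D were higher in tumour 3, KRT13 at 25.4 against 0.126 cp10k (201-fold, interval 147 to 4375) and SPRR2D at 1.89 against 0.00204 (924-fold, interval 9.37 to 2063). Chemokines were higher in tumour cells of tumour 1 by a median of 3.31 (9 of 9) and metallothioneins by 1.90 (5 of 5), and immediate-early and heat shock genes were higher in tumour 3 (-1.68, 11 of 11). The M1-like (1.73, 8 of 9) and cytotoxic lists (1.77, 3 of 4) were also higher in tumour 1. The M2-like (-0.69, 5 of 7) and checkpoint lists (-0.76, 3 of 4) were lower, and immune RNA in the 68 cells was not separated.

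Day 0 immune cells of the 2 tumours were compared in the same way. In macrophages the ciliary gene DNAAF1 was 57.1-fold higher in tumour 1 (2.29 against 0.0400 cp10k), the histone HIST2H2AA4 36.1-fold and PTPRCAP, a partner of the phosphatase CD45, 24.3-fold, along with the antibody genes IGHM (60.5-fold) and JCHAIN (28.5-fold). The B cell genes TNFRSF13C (250-fold, interval 33.5 to 7827, 1 UMI in tumour 3) and MS4A1 (46.3-fold), the mast cell gene TPSAB1 (41.3-fold) and the haemoglobin gene HBA2 (at least 164-fold) were higher too. LUM of fibroblasts (146-fold, interval 11.7 to 2622) and KRT19 of epithelium (45.6-fold, interval 11.2 to 2499) were lower, with 1 UMI each in tumour 1. The macrophage class thus holds RNA of other cells of its tumour, and the matrix difference below is not a property of macrophages alone. The platelet chemokine PPBP had no UMI in macrophages of tumour 1 against 0.889 cp10k in tumour 3 (at least 72.6-fold). Hypoxia genes (-0.65, 9 of 10), matrix genes (-1.44, 9 of 10, -0.50 after thinning) and chemokines (-0.88, 10 of 13) were lower in macrophages of tumour 1, and Type I interferon genes higher (0.55, 10 of 14). T cells of tumour 1 had higher medians for checkpoint (1.36, 8 of 9), cytotoxic (1.26, 8 of 10), activation (1.63, 7 of 7) and naive and memory genes (1.62, 7 of 7), lower ones for proliferation (-0.98, 11 of 12), hypoxia (-0.98, 8 of 8) and immediate-early and heat shock genes (-1.05, 10 of 11), and PTPRCAP at 5.71 against 0.146 cp10k (39.0-fold). Without C1Q-positive cells the first 4 medians were 0.64, 0.38, 1.02 and 0.93. The T cells of tumour 3 carried RNA of its other cells, with KRT19 at 3.21 cp10k against none in tumour 1 (at least 233-fold) and matrix genes lower in tumour 1 at -4.77 (-1.58 at a mitochondrial limit of 5%), RNA that takes up part of every T cell count there.

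At the later days the 2 tumours were compared class by class, with tumour and day of sampling changing together and the tables normalized separately. In NK cells HOXB5 (0.0398 against 0.00087 cp10k, 45.8-fold), the adhesion receptor ADGRE2 (39.2-fold), the histamine receptor HRH2 (0.173 against 0.00693, 25.0-fold) and the cystine transporter SLC7A11 (0.115 against 0.00496, 23.2-fold) were higher at day 7 of tumour 1. The antibody gene JCHAIN (28.1-fold) and CXCL8 (27.2-fold) were lower there, as were IGHG1 (41.9-fold, interval 64.0 to 133) and IGLC2 (34.0-fold, interval 49.6 to 87.8), which rest mostly on 1 tumour 3 library (0.0149 to 0.114 and 0.00947 to 0.144 cp10k across its libraries). Metallothioneins were higher by a median of 1.92 (6 of 6). CD8 T cells of tumour 1 had more S100B (0.184 against 0.00291 cp10k, 63.1-fold), NPTX1 (48.6-fold) and REG4 (0.176 against 0.00788, 22.3-fold) and less of the interleukin 1 antagonist IL1RN (0.00346 against 0.183, 53.1-fold), HTRA1 (31.9-fold) and INHBA (22.2-fold). Their Type I interferon genes were higher by 0.66 (11 of 13) and proliferation genes by 0.77 (12 of 12), and activation genes lower (-0.77, 6 of 7).

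Conventional CD4 T cells of tumour 1 had higher Type I interferon genes (1.18, 12 of 12), led by IFI44L at 0.200 against 0.0291 cp10k (6.85-fold), and lower cytotoxic (-1.32, 9 of 11, -0.47 from summed UMIs) and proliferation genes (-1.13, 12 of 12). The type 2 cytokine IL4 was 0.00892 against 0.421 cp10k (47.2-fold lower), FOS 0.0355 against 1.22 (34.3-fold, interval 15.7 to 22.4) and the lysophospholipase ENPP2 424-fold lower (33.0 to 7349.9). Later macrophages of tumour 1 had more of the BMP antagonist GREM1 (1.03 against 0.0431 cp10k, 23.8-fold), the steroid-reducing enzyme AKR1C1 (20.1-fold), MMP7 (1.5 against 0.0988, 15.2-fold) and MT1M (10.8-fold). The chemokines CCL1 (0.0918 against 2.35 cp10k, 25.6-fold) and CCL18 (0.505 against 5.0, 9.90-fold), CXCL1 (9.32-fold) and the scavenger receptor MARCO (9.84-fold) were lower. Their metallothionein median was 1.41 (6 of 6), Type I interferon median 0.96 (10 of 11) and chemokine median -1.95 (8 of 9 lower, -0.40 after thinning).

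What the later undefined cells are was examined against NK cells of the same libraries. They expressed cytokine and receptor genes that were scarce in NK cells: IL23R, the receptor for interleukin 23, was 309-fold higher in tumour 1 (0.524 cp10k) and 179-fold higher in tumour 3 (0.941 cp10k). IL26 was 334-fold and 274-fold higher, the amino acid oxidase IL4I1 116-fold and 132-fold and LINGO4 725-fold and 195-fold. Carbonic anhydrase CA2 was 199-fold and 161-fold higher, MATN2 222-fold and 92.0-fold, KIAA1217 116-fold and 169-fold, ADAM12 121-fold and 97.1-fold and AFAP1L1 165-fold and 87.6-fold. NK genes were lower, such as KLRF1 (17.5-fold and 19.9-fold), the Fc receptor FCGR3A (12.6-fold and 29.5-fold), SPTSSB (25.7-fold and 34.7-fold), WNT11 (25.3-fold and 23.3-fold) and GEM (13.5-fold and 15-fold). The cytotoxic list was lower at -2.96 (-4.20 without the top 6% of doublet scores) and -1.96, and interferon-gamma targets (1.80 and 1.42), Type I interferon genes (1.86 and 0.53, the latter 1.58 after thinning) and MHC class I genes (0.96 and 0.44, 10 of 10 in both) were higher.

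Regulatory T cells were compared with conventional CD4 T cells, since tremelimumab binds a receptor they carry. FOXP3, which defines them, was 4.96 against 0.171 cp10k in tumour 1 (29.0-fold) and 3.25 against 0.315 in tumour 3 (10.3-fold). LRRC32, which holds latent TGF-beta on the cell surface, was 58.0-fold and 12.2-fold higher, and RTKN2 14.7-fold and 10.8-fold. EPHB1 (45.1-fold and 21.1-fold), METTL7A (22.6-fold and 14.9-fold), MEOX1 (20.1-fold and 13.4-fold), FCRL3 (26.3-fold and 11.4-fold), HDAC9 (10.8-fold and 13.4-fold), CD40 (9.52-fold and 15.6-fold) and the interferon gene IFI27 (9.33-fold and 11.5-fold) were higher as well. In tumour 3 the regulatory T class also held dendritic cell RNA, with more than 9 UMIs of 6 dendritic genes in 20 of 459 cells, and CD40 is a gene of dendritic cells too. IL17RB, a receptor of type 2 helper cells, was 32.0-fold and 88.4-fold lower, ADGRG1 10.2-fold and 15.9-fold and PTPN13 60.6-fold and 8.67-fold. Type I interferon genes were higher by 1.00 and 1.70 and interferon-gamma targets by 0.94 and 0.96, and proliferation genes were near even in tumour 1 (-0.12) but lower in tumour 3 (-3.69).

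NK cells were compared with CD8 T cells, the other killer class. SPTSSB (37.6-fold and 51.5-fold), IGFBP7 (36.6-fold with an interval of 17.0 to 21.9, and 17.0-fold), the stem cell factor receptor KIT (13.6-fold and 14.5-fold) and the receptor KLRF2 (26.1-fold and 14.7-fold) were higher in NK cells. The T cell receptor partners CD3G (37.9-fold and 23.2-fold) and CD3D (20.7-fold and 22.9-fold), CD8B (57.2-fold and 20.8-fold), CD5 (29.0-fold and 22.6-fold) and the transcription factor ETV1 (37.4-fold and 23.3-fold) were lower. Naive and memory genes (-3.24 and -1.35), MHC class II genes (-2.11 and -1.71, 10 of 10 in both) and checkpoint genes (-1.81 and -1.10) were lower in NK cells, and proliferation genes were slightly higher (0.27 and 0.84).

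Where the drug targets were expressed was read in each class, whatever the UMI count. CD274, the target of durvalumab, was highest at day 0 in CD14-negative myeloid cells, at 0.259 and 0.486 cp10k in tumour 1 and tumour 3, against 0.105 and 0.174 in macrophages and 0.189 and 0.115 in T cells. These myeloid values rest on 43 and 34 UMIs. In tumour 1 the interval per 10000 summed UMIs (0.184 to 0.343) overlaps that of T cells (0.123 to 0.240, 38 UMIs). Later CD274 was highest in myeloid cells, at 0.597 (0.532 to 0.701) and 0.432 (0.376 to 0.488) cp10k, followed in tumour 1 by the class named for CCL17, CCL22 and T cells (0.357), against 0.00723 and 0.00920 in NK cells. CTLA4, the target of tremelimumab, was 3.11 and 0.769 cp10k in day 0 T cells, and later 0.99 and 1.94 in regulatory, 0.392 and 1.54 in conventional CD4 and 0.169 and 0.342 in CD8 T cells. In tumour 3 the conventional CD4 level of CTLA4 ran from 0.520 to 1.90 cp10k across libraries. PDCD1, the receptor that PD-L1 binds, was 0.694 and 0.271 cp10k in day 0 T cells, and later highest in conventional CD4 T cells (1.06 and 0.839), followed by CD8 T cells (0.671 and 0.317), with 0.343 in the class of tumour 1 named for CCL17, CCL22 and T cells and 0.197 and 0.204 in regulatory T cells.

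**Figure D3:**
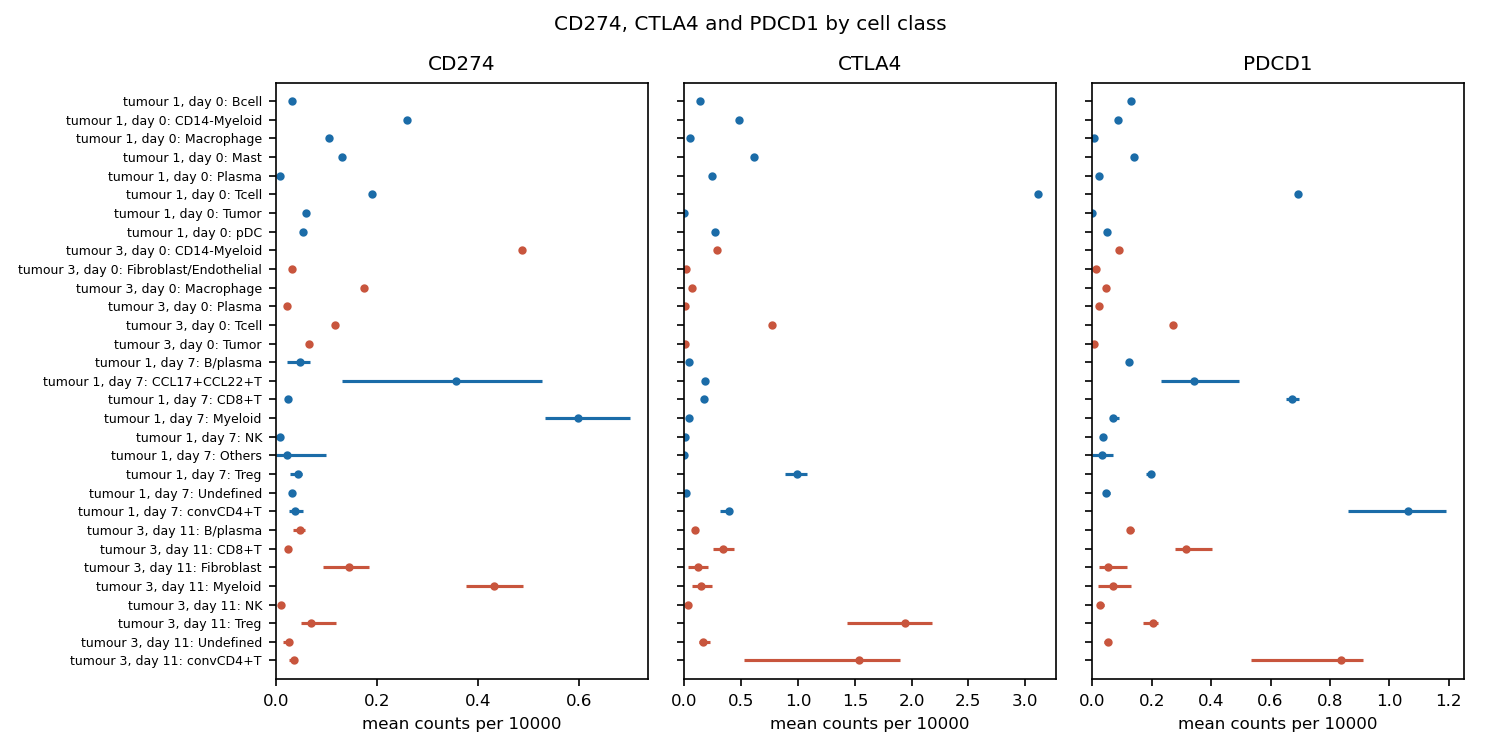
Mean level of CD274, CTLA4 and PDCD1 in each cell class and tumour, in counts per 10000. Dots are means over all cells of a class, and lines run from the lowest to the highest library. The day 0 and later tables were normalized separately.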

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

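The list differences between tumours below were picked after the results were seen, and none of them was tested.

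Naive and memory genes of T cells, later day against day 0, had a median log2 ratio of -0.39 in tumour 1 (-0.50 to -0.23 across libraries) and 1.13 in tumour 3 (0.82 to 1.35), and the difference was not tested. The tumour 3 value had the other sign after thinning (-0.12) and was 0.36 without C1Q-positive day 0 cells and 0.19 with NK cells added to the later T cells. T cell activation genes had -1.16 (-1.20 to -1.09) in tumour 1 and 1.22 (0.83 to 1.48) in tumour 3, also untested, and 0.42 in tumour 3 without C1Q-positive cells. Proliferation genes of T cells had 0.84 (0.70 to 0.95) and -0.30 (-1.18 to -0.03), again without a test. The day 0 side in tumour 3 is 44 T cells, many with myeloid RNA, and no biological explanation was tested because the design gives 1 tumour per later day.

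MHC class II genes of B and plasma cells had a median of -0.21 (-0.38 to -0.03) in tumour 1 and 2.94 (2.58 to 3.40) in tumour 3, and the difference was not tested. Day 0 held 262 B cells in tumour 1 and 2 in tumour 3, and plasma cells express little MHC class II.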

How the results depend on the processing

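Thinning each cell to 500 UMIs, a mitochondrial limit of 10%, a minimum of 1000 UMIs and keeping doublets were chosen before the data were examined. Every other setting was chosen after the data were seen: summed UMIs, a mitochondrial limit of 5%, the top doublet scores, day 0 T cells without those holding 2 or more C1Q UMIs, NK cells added to later T cells, CD14-negative myeloid cells added to macrophages and leaving out each later library.

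No paired analysis was possible because the values come from no test, so there was no fitted result to repeat with pairs. Each tumour's later libraries were set against its own day 0 library. The design itself did not prevent a fit of the later day against day 0 with the tumour as a block. Such a fit was not planned and was not run. Leiden clustering at a resolution of 0.5, the edgeR, DESeq2 and camera alternatives and leaving out each tumour were not run. A minimum of 1000 UMIs left out no cell. A mitochondrial limit of 10% kept 13758 of 13759 cells of tumour 3 at day 11 and all cells elsewhere. Neither setting could therefore move results much. No list median moved past its bound with CD14-negative myeloid cells added to the macrophages, and shares were not recomputed there. A share moved if it left its counting interval, and a list median if it moved by more than the width of its library range, or 1.5-fold where each side has 1 library. The width can be large. CD14-negative myeloid cells moved a median by up to 1.08 log2 units, and leaving out a library by up to 1.01. The medians of comparisons other than later day against day 0 were recomputed, and the 1.5-fold bound was set, after the data were seen.

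The 1139 list medians over all settings include 111 at the mitochondrial limit of 10% and 111 at the minimum of 1000 UMIs, which left out almost no cell. Of the 1139, 26 had the other sign. Only 2 of these had been 0.5 or more from zero with all libraries on 1 side: in T cells of tumour 3, interferon-gamma targets were 0.11 instead of -0.82 without C1Q-positive cells, and naive and memory genes were -0.12 instead of 1.13 after thinning. The first version of thinning, which put the floor on any side without UMIs, changed the sign of 70 of 391 named genes. Genes without enough UMIs were then given no ratio, and none of the 319 named genes that kept a ratio had the other sign.

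With NK cells added, later T cells of tumour 1 had medians of 1.63 for cytotoxic, -2.64 for Type I interferon, -1.65 for checkpoint, -1.68 for naive and memory, -1.98 for activation, -0.39 for MHC class I, 1.34 for proliferation, -5.10 for immediate-early and -0.79 for interferon-gamma genes, and those of tumour 3 had 0.19 for naive and memory genes. Without C1Q-positive cells, T cells of tumour 3 had -1.06 for Type I interferon, 0.85 for cytotoxic, -0.32 for checkpoint, 0.36 for naive and memory and 0.42 for activation genes, and Type I interferon was -1.81 in tumour 1.

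Thinning moved 38 of 109 list medians. T cells of tumour 1 then had 0.44 for metallothioneins, -5.50 for immediate-early, -0.95 for checkpoint, 0.71 for cytotoxic and -2.19 for Type I interferon genes, and T cells of tumour 3 had 1.30 for cytotoxic and -0.23 for interferon-gamma genes. B and plasma cells had 1.34 for interferon-gamma, 2.15 for proliferation and -5.72 for immediate-early genes in tumour 1, and -1.41 for Type I interferon and 1.97 for interferon-gamma genes in tumour 3. Fibroblasts had 0.87 for interferon-gamma genes. Macrophages of tumour 1 had 1.71 for proliferation, -1.35 for Type I interferon, -1.70 for M2-like, -0.44 for hypoxia and -5.15 for immediate-early genes, and those of tumour 3 had 3.64 for cytotoxic, 1.31 for proliferation, -3.84 for immediate-early, -3.67 for chemokine, -2.10 for M2-like, -2.62 for M1-like and -1.35 for Type I interferon genes. Of the 319 named genes, 230 moved by more than 1 log2 unit. This held for 37 of 57 without C1Q-positive cells (by up to 8.86), 10 of 40 with NK cells added, 4 of 40 with CD14-negative myeloid cells added, 77 of 400 at 5% mitochondrial RNA, 51 of 400 from summed UMIs, 45 of 400 without the top doublet scores, 6 of 400 with doublets kept, and 24, 41 and 25 of 340 on leaving out a library, and none had the other sign.

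With cells above 5% mitochondrial RNA left out, tumour 1 at day 7 had 26.4% CD8, 4.57% regulatory and 11.2% conventional CD4 T cells, 50.1% NK, 3.52% B and plasma and 1.40% myeloid cells. Tumour 3 at day 11 had 46.8% NK, 9.38% undefined, 4.09% regulatory T, 1.35% myeloid and 18.3% CD8 T cells, and at day 0 6.60% plasma and 31.6% tumour cells. The proliferation median of B and plasma cells in tumour 1 was 3.45, T cells of tumour 1 had -0.17 for metallothioneins, -1.53 for checkpoint and 0.58 for cytotoxic genes, and the chemokine median of macrophages in tumour 3 was -3.45. Leaving out the top 6% of doublet scores gave 9.43% undefined and 46.5% NK cells in tumour 3 at day 11, 2.92% regulatory T cells in tumour 1 at day 7 and a checkpoint median of -1.10 in its T cells.

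From summed UMIs, T cells of tumour 1 had -2.21 for Type I interferon and -0.045 for MHC class I genes, B and plasma cells of tumour 1 had 1.33 for interferon-gamma, -1.06 for Type I interferon, 4.91 for proliferation and -5.69 for immediate-early genes, and macrophages of tumour 3 had -4.30 for chemokines. Leaving out each later library gave 62.9% to 64.1% NK and 7.06% to 8.15% conventional CD4 T cells in tumour 1. In tumour 3 it gave 41.1% to 49.2% NK, 19.6% to 21.5% CD8, 12.3% to 19.7% conventional CD4 and 2.43% to 3.93% regulatory T cells, 9.79% to 10.7% undefined and 0.849% to 1.16% myeloid cells, and a macrophage chemokine median of -3.80 to -3.17.

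Between the tumours at day 0, the T cell medians without C1Q-positive cells were 0.38 for cytotoxic, 0.64 for checkpoint, 0.93 for naive and memory and 1.02 for activation genes. Thinning gave T cells 0.55 for cytotoxic, 0.71 for checkpoint and -3.78 for matrix genes, and macrophages -0.50 for matrix genes. The T cell matrix median was -5.49 with doublets kept and -1.58 at 5% mitochondrial RNA. Between the tumours at the later days, thinning gave 1.5 for metallothioneins in NK cells, -0.53 for activation in CD8 T cells, 1.57 for Type I interferon in conventional CD4 T cells, and 0.48 for Type I interferon, -0.40 for chemokines and 1.03 for metallothioneins in macrophages. CD8 proliferation was 0.47 at 5% mitochondrial RNA, conventional CD4 cytotoxic genes were -0.47 from summed UMIs, and macrophage Type I interferon was 1.10 without the top doublet scores. Leaving out a library gave 0.51 to 1.01 for CD8 proliferation and 0.84 to 1.87 for macrophage metallothioneins.

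For undefined against NK cells, cytotoxic medians were -2.45 and -1.71 from summed UMIs and -4.20 and -2.42 without the top doublet scores. MHC class I in tumour 1 was 1.05 after thinning and 1.05 at 5% mitochondrial RNA, and Type I interferon in tumour 3 was 1.58 and 0.90. Leaving out a library gave 1.67 to 1.88 for Type I interferon in tumour 1 and -2.13 to -1.96 for cytotoxic genes in tumour 3. For regulatory against conventional CD4 T cells of tumour 1, interferon-gamma targets were 0.90 at 5% mitochondrial RNA, 0.77 from summed UMIs and 0.85 to 0.94 on leaving out a library, and proliferation was -0.52 without the top doublet scores. For NK against CD8 T cells, naive and memory genes in tumour 1 were -2.86 at 5% mitochondrial RNA, -3.06 from summed UMIs and -3.48 without the top doublet scores. In tumour 3 they were -1.56 at 5% mitochondrial RNA, -1.22 from summed UMIs, -1.82 after thinning and -1.48 to -1.25 on leaving out a library. MHC class II in tumour 1 was -1.86 at 5% mitochondrial RNA.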

Other observations

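All 8 checks of explanations below were chosen after the results were seen. The checks of depth, leaked RNA and mast cells were redone after a first version, which had counted 11 of 11 list genes lower at the later day, read the ratio in tumour 3 only and left mast cells open.

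The day 0 CD14-negative myeloid cells carried dendritic cell RNA, with CD1C, CCL17 and CCL22 among their leading genes in both tumours and CCL17 at 8.22 cp10k in tumour 3. Their HLA-DRA was 86.1 cp10k in tumour 1 and 106 in tumour 3, and CD74 215 and 226. Both genes were above the macrophage level in tumour 1 and below it in tumour 3, so they do not set the class apart. Plasmacytoid dendritic cells of tumour 1 had LILRA4 at 3.40, GZMB at 22.0 and JCHAIN at 13.7 cp10k, and its mast cells had TPSB2 at 101 and CPA3 at 55.7 cp10k.

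Lower immediate-early and heat shock genes at the later day were seen in every class compared. A shared pool of leaked RNA as the whole cause would give every day 0 class of a tumour the same HSPA1A to FOS ratio, but it ran from 0.570 in B cells to 2.87 in plasma cells of tumour 1 and from 2.31 in fibroblasts and endothelial cells to 8.08 in plasma cells of tumour 3, a spread of 5.04 and 3.5, and a smaller part from leaked RNA stays open. With every cell thinned to 500 UMIs, the list median nearest to 0 in any class and tumour was -3.84. Thinning leaves the expected share of a gene in a cell's UMIs unchanged, so this check cannot decide on depth, which stays open. Handling of the fresh biopsy may explain the lower list genes and stays open, with 0 libraries holding cells of both days. No biological explanation was tested.

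The class of tumour 1 named for CCL17, CCL22 and T cells expressed CCL17 at 14.5, CCL22 at 11.3, FSCN1 at 9.63 and LAMP3 at 3.70 cp10k, the pattern of mature dendritic cells, beside CD8A at 1.75. Doublets of a dendritic cell and a T cell could explain the T cell part: cells with more than 10 UMIs of 5 T cell genes had a median of 22902 UMIs and cells with at most 2 had 10769, a ratio of 2.13. The split on a raw count itself favours deeper cells in the higher group, so this ratio alone cannot show doublets. Over 6 dendritic genes the same groups had medians of 43.5 and 38 UMIs, a ratio of 1.14. Free T cell RNA spread evenly over the class was excluded as the whole cause, since 25.1% of the 183 cells held none of it where chance would leave 0.00635%. That chance share rests on the class mean, which the cells with more than 10 such UMIs raise, so a smaller part from free RNA stays open.

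The undefined class could be group 3 innate lymphoid cells, with KIT at 2.32 and 2.30, NCR2 at 0.871 and 1.42 and IL23R at 0.524 and 0.941 cp10k in tumour 1 and tumour 3. A first count over all 14 genes of the list found 9 highest in this class in both tumours, but some had been seen beforehand. Of the 9 genes not seen before, 4 were highest there (AHR, TNFSF4, ID2 and CXXC5), which leaves the identity open, and IL22 was only 0.00753 and 0.000818 cp10k. T cells were excluded, as the highest of CD3D, CD3G, CD5 and CD6 reached 0.0977 of the conventional CD4 T cell level, and mast cells because TPSAB1 had no UMI in tumour 1 and HDC stood at no more than 0.000159 of its level in day 0 mast cells in either tumour, though only 2 of 5 mast cell genes are listed.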
